A study of Homo sapiens with 12 samples.

How the data were processed

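Messenger RNA of T47D cells was sequenced in a control line (CTRL) and an NF1 knockout line (NF1KO), each treated with DMSO or 3 µM BYL719 for 48 h. Per the labels, the authors aligned reads to hg38 with STAR 2.5.2a, processed alignments with SAMtools 1.7 and Picard 2.9.2, and used edgeR. The deposited table holds raw counts per Entrez gene, and neither the counting tool nor the gene annotation was stated. It holds 27864 genes and 11 libraries of 53283945 to 60148876 counts, of which 20 ribosomal RNA genes took between 8.45% and 12.3%. Of 12 labelled samples, NF1KO DMSO replicate 1 was not analysed here. Of the Entrez identifiers, 27740 (99.6%) matched RefSeq on GRCh38, which gave positions, and 63 had no symbol.

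Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, which left 16081, and libraries were scaled by TMM. A quasi-likelihood model with the 4 groups and 7 residual degrees of freedom was used for 5 comparisons: knockout against control in each treatment, BYL719 against DMSO in each line, and the difference of the BYL719 effect between the lines. Tests were 2-sided, p values were adjusted by Benjamini-Hochberg over the tested genes of a comparison, and an adjusted p under 0.05 was called. The SE of a log2 fold change was its size divided by the square root of its F statistic. CPM values used TMM-scaled library sizes, and their error is the SD between replicates.

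There were 26 gene lists, of which 25 could be measured, since the mitochondrially encoded list had no member in the table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, in a single direction and does not compare them with other genes. Members called were counted over all genes tested and adjusted over the list alone. The BYL719 response score was the mean log2 CPM (prior count 2) of raised less that of lowered genes, chosen by the average BYL719 effect over both lines with an adjusted p under 0.05 and a fold above 1.5. Its difference between lines was tested by permuting residuals within treatments over all 200 arrangements.

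Named genes were NF1, and per comparison the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2, a symbol other than a LOC, clone, LINC, antisense, pseudogene or RNA-only name and, except for the difference of effects, no overlap between the groups. Up to 4 members per list described, by adjusted p, were named as well. The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. A gene whose annotated position overlaps another gene with at least 20% of its counts is pointed out.

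Alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the compared libraries, and leaving out each library in turn. Leaving out an NF1KO DMSO library left 1, which was assumed to vary like the other groups. A block within each genotype, leaving out both CTRL number-1 libraries and leaving NF1 out of its list were added after the data were seen. In the fit with that block, knockout against control compares the fitted levels of replicate 3, so it is not an alternative estimate of the line difference. Whether equal replicate numbers pair libraries was checked from the deviations of each library from its group over genes. For CTRL DMSO and BYL719 libraries of the same number these correlated at 0.59, 0.34 and 0.32 across genes, which are not independent replicates. CTRL DMSO replicate 2 with BYL719 replicate 3 correlated at 0.23 and DMSO replicate 3 with BYL719 replicate 2 at 0.18, so that the pairing of numbers 2 and 3 is less clear than that of number 1. The 2 same-number NF1KO pairs correlated at 0.08 and 0.15. Deviations of the 2 NF1KO DMSO libraries mirror each other exactly, so these values can hardly show pairing. NF1KO DMSO replicate 2 also correlated at 0.08 with BYL719 replicate 1, and the other different-number NF1KO pairs lay between -0.15 and -0.08.

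The steps were tested on simulated counts with the same mean in each group, apart from a small set of genes changed by known folds. Counts varied independently between libraries, without pairs or outlying libraries, and the real comparisons called far more genes. The shares below therefore need not hold for the real comparisons. Of genes changed 2-fold, 82.1% were called for knockout against control in DMSO, 86.6% for BYL719 in CTRL, 85.1% for BYL719 in NF1KO, 92.5% for knockout against control in BYL719 and 74.6% for the difference of effects, and false calls made up 6.17%, 3.70%, 3.73%, 7.10% and 1.55%. Of genes changed 1.5-fold in the difference of effects, 29.9% were called. Figures were drawn with matplotlib 3.10.9.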

Results

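Messenger RNA was measured by RNA sequencing in T47D cells, an established estrogen receptor-positive breast cancer line, in a control line (CTRL) and a line in which NF1 had been knocked out (NF1KO). NF1 encodes neurofibromin, a GTPase-activating protein that switches RAS off. Both lines were treated for 48 h with the vehicle DMSO or with 3 µM BYL719 (alpelisib), an inhibitor of the alpha isoform of PI3K. The 4 groups held 3 CTRL DMSO, 3 CTRL BYL719, 2 NF1KO DMSO and 3 NF1KO BYL719 libraries, since NF1KO DMSO replicate 1 was not analysed here. The 11 libraries held between 53283945 and 60148876 counts each. In all, 16081 of the 27864 genes in the table had enough counts to be tested. Values per group are normalised read counts (CPM) with their SD, and differences between groups are log2 fold changes with their SE, from 2-sided tests. Replicates were libraries of the control line or of the knockout line, so their spread does not measure how independent knockouts would differ. A difference between the lines therefore cannot be put down to NF1 alone.

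NF1 mRNA (Entrez gene 4763, chromosome 17, 31094977 to 31377675, GRCh38) was almost gone from the knockout line. It stood at 249 ± 39.6 CPM (SD, n = 3) in CTRL and 0.475 ± 0.00633 CPM (SD, n = 2) in NF1KO in DMSO, where the knockout held 0.191% of the control level. In BYL719 it stood at 171 ± 37.1 CPM (SD, n = 3) in CTRL and 0.613 ± 0.252 CPM (SD, n = 3) in NF1KO, or 0.359%. The log2 difference was -9.03 ± 0.32 in DMSO (adjusted p = 2.51e-09) and -8.11 ± 0.25 in BYL719 (adjusted p = 3.93e-10), and each NF1KO library lay far below each CTRL library. In CTRL, BYL719 lowered NF1 by a log2 change of -0.55 ± 0.16 (adjusted p = 0.0176). That call was lost without CTRL DMSO replicate 1 (adjusted p = 0.0563), CTRL BYL719 replicate 2 (0.0728) or CTRL BYL719 replicate 3 (0.0719).

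**Figure D1:**
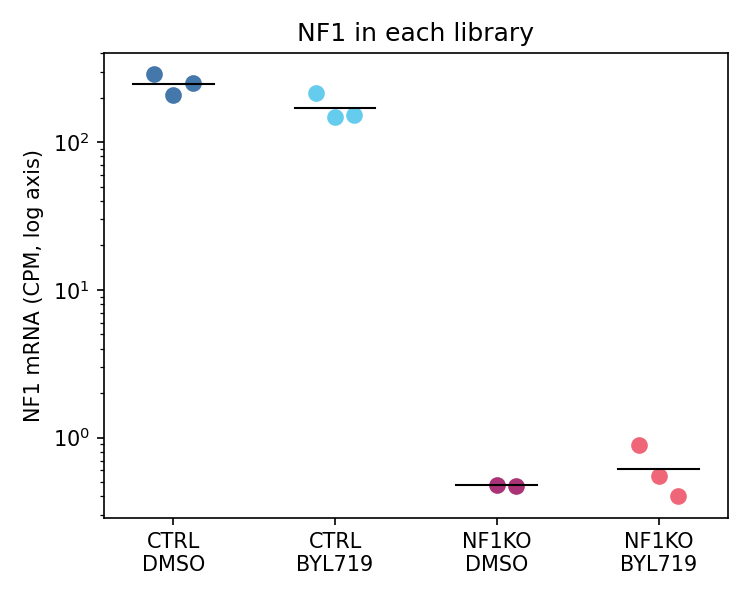
NF1 mRNA in each library (points, CPM on a log axis) with the mean of each group (lines). The 5 NF1KO libraries lie between 0.40 and 0.891 CPM and the 6 CTRL libraries between 147 and 289 CPM.

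The comparison of NF1KO with CTRL in DMSO asks what differs between the lines before drug. Several targets and feedback regulators of the RAS-ERK pathway were far higher in NF1KO. SPRY4 (Entrez 81848, chromosome 5, 142310430 to 142325021), a feedback inhibitor of receptor signalling, rose from 0.285 ± 0.154 CPM (SD, n = 3) in CTRL to 20.2 ± 0.192 CPM (SD, n = 2) in NF1KO, a log2 change of 6.15 ± 0.23 (adjusted p = 3.51e-09). ETV5 (Entrez 2119, chromosome 3, 186046314 to 186109089), an ETS transcription factor, rose by 6.11 ± 0.20 (adjusted p = 1.53e-09), and DUSP6 (Entrez 1848, chromosome 12, 89347235 to 89352501), a phosphatase that inactivates ERK, rose by 4.58 ± 0.19 (adjusted p = 1.25e-08). CALCR (Entrez 799, chromosome 7, 93424486 to 93574724), the calcitonin receptor, fell from 16.4 ± 0.467 CPM (SD, n = 3) to 0.347 ± 0.0471 CPM (SD, n = 2), a log2 change of -5.56 ± 0.14 (adjusted p = 2.71e-10). TGFB2 (Entrez 7042, chromosome 1, 218345336 to 218444619), a TGF-beta ligand, changed by -4.77 ± 0.15 (adjusted p = 1.53e-09).

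The other large rises were of DOK7 (5.54 ± 0.23), an activator of the kinase MuSK, the muscle ubiquitin ligase TRIM55 (5.52 ± 0.19), the diamine oxidase AOC1 (5.37 ± 0.19), PLXDC2 (5.18 ± 0.17), CLSTN2 (4.81 ± 0.15), the Wnt receptor ligand NDP (4.79 ± 0.21) and the endocytic receptor LRP2 (4.39 ± 0.19). The other large falls were of ARMCX1 (-4.43 ± 0.17), the matrix proteoglycan VCAN (-4.19 ± 0.20), the GDNF co-receptor GFRA1 (-3.87 ± 0.09), PHACTR1 (-3.77 ± 0.12), TENM3 (-3.35 ± 0.10), the G protein subunit GNG11 (-3.26 ± 0.13) and the phospholipase PLCE1 (-3.18 ± 0.26). Adjusted p values of these 14 genes lay between 1.63e-10 and 3.16e-06. In all, 1607 genes were higher and 1662 lower in NF1KO, of which 453 and 455 by more than 2-fold. With a filter of at least 1 CPM in at least 3 libraries, 300 rather than 453 were more than 2-fold higher. Far fewer genes were called without either NF1KO DMSO library, a fit that leaves a single library in that group. With the replicate number as a block within each genotype, added after the data were seen, 2753 genes were higher and 2774 lower. That fit compares the lines at replicate 3 alone, so these are not an alternative count of the line difference. The annotated positions of TGFB2, PHACTR1, TENM3 and PLCE1 overlap another gene whose counts were 20.3%, 241%, 21.8% and 282% of their own, and how such reads were counted is not known.

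Of the 20 ERK pathway output genes, 16 rose and 1 fell in NF1KO, also when adjusted over the list alone (adjusted p = 5.53e-34 for the list, adjusted p = 0.00119 with an estimated correlation). The smallest p belonged to the ERK phosphatase DUSP4, which rose by 3.97 ± 0.09 (adjusted p = 8.67e-11). Genes of the integrated stress response and amino acid supply leaned upward, with 13 of 23 higher and 3 lower (15 and 3 when adjusted over the list alone, adjusted p = 0.00903 for the list, adjusted p = 0.545 with an estimated correlation). The glutathione-degrading enzyme CHAC1 rose by 2.27 ± 0.20 and the glutamine transporter SLC1A5 by 0.70 ± 0.07, while the amino acid transporter SLC7A5 changed by -1.03 ± 0.07. Among 17 apoptosis regulators 6 rose and 1 fell (6 and 2 when adjusted over the list alone, adjusted p = 0.0271 for the list, adjusted p = 0.545 with an estimated correlation). The survival factor BCL2 rose by 1.63 ± 0.13 and the cell-cycle inhibitor CDKN1A by 1.32 ± 0.13. The apoptosis call was lost with the replicate block (adjusted p = 0.0522), without both CTRL number-1 libraries (0.0733) and without CTRL DMSO replicate 1 (0.0596).

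Hypoxia response genes were lower in NF1KO, with 6 of 18 lower and 0 higher (9 and 0 when adjusted over the list alone, adjusted p = 0.000407 for the list, adjusted p = 0.239 with an estimated correlation). NDRG1 changed by -2.97 ± 0.19, the carbonic anhydrase CA9 by -2.35 ± 0.25 and the peptide hormone ADM by -1.52 ± 0.20. Among 16 receptor tyrosine kinases 7 were lower and 4 higher (8 and 4 when adjusted over the list alone, adjusted p = 0.0271 for the list, adjusted p = 0.313 with an estimated correlation, and 0.105 without NF1KO DMSO replicate 2). MET changed by -1.36 ± 0.07, FGFR2 by -1.03 ± 0.09 and ERBB2, which encodes HER2, by -0.82 ± 0.10, and EPHA1 rose by 0.57 ± 0.07. The list of 11 RAS GTPase-activating proteins holds NF1 itself, and its call (4 lower and 1 higher, 5 and 1 when adjusted over the list alone, adjusted p = 0.00754, adjusted p = 0.545 with an estimated correlation) was lost when NF1 was left out of it (adjusted p = 0.567). Of the other 10 members, 3 were lower and 1 higher. RASA3 changed by -0.51 ± 0.12 and RASAL1 by 1.04 ± 0.27. The luminal transcription factors ESR1, which encodes the estrogen receptor, and FOXA1 changed by -0.83 ± 0.09 (adjusted p = 3.30e-05) and -0.39 ± 0.07 (adjusted p = 0.00113). In the luminal list 3 of 15 genes were lower and 1 higher (3 and 3 when adjusted over the list alone, median 0.11). The luminal list as a whole was not called (adjusted p = 0.801). Cell-cycle lists were not called in DMSO, with 1 of 27 S phase genes higher and 1 lower (adjusted p = 0.824) and 1 of 27 G2/M genes higher and 2 lower (adjusted p = 0.475).

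**Figure D2:**
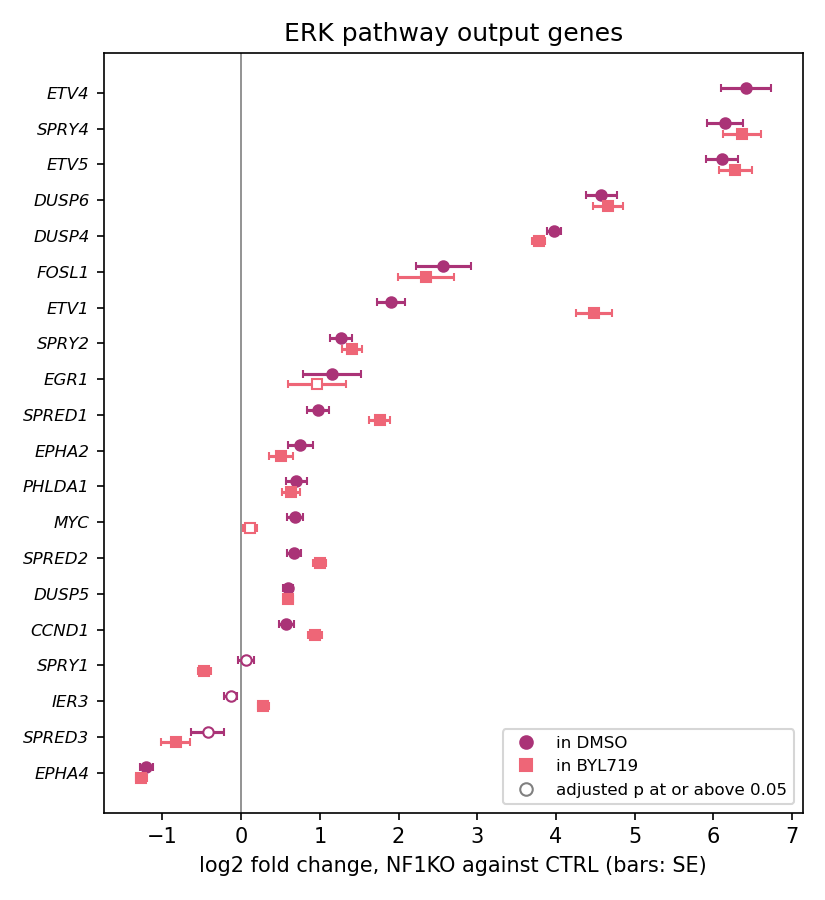
Log2 fold change (points, with SE bars) of the 20 ERK pathway output genes between NF1KO and CTRL, in DMSO (circles) and in BYL719 (squares), with open symbols where the adjusted p was at or above 0.05. SPRY4, ETV5, DUSP6 and DUSP4 rose by 3.78 to 6.36 in both treatments, and ETV4 has no BYL719 point because the 3 CTRL libraries there held 0 counts of it.

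CALCR, GNG11 and MET lie within a stretch of chromosome 7 (90119400 to 117230176) picked out after the values were seen, in which most genes were lower in NF1KO. Of its 191 tested genes, 174 had a log2 fold change below 0 in DMSO and 175 in BYL719, with medians of -0.48 and -0.52. CALCR, GNG11 and MET each fell by more than the median in both treatments.

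**Figure D3:**
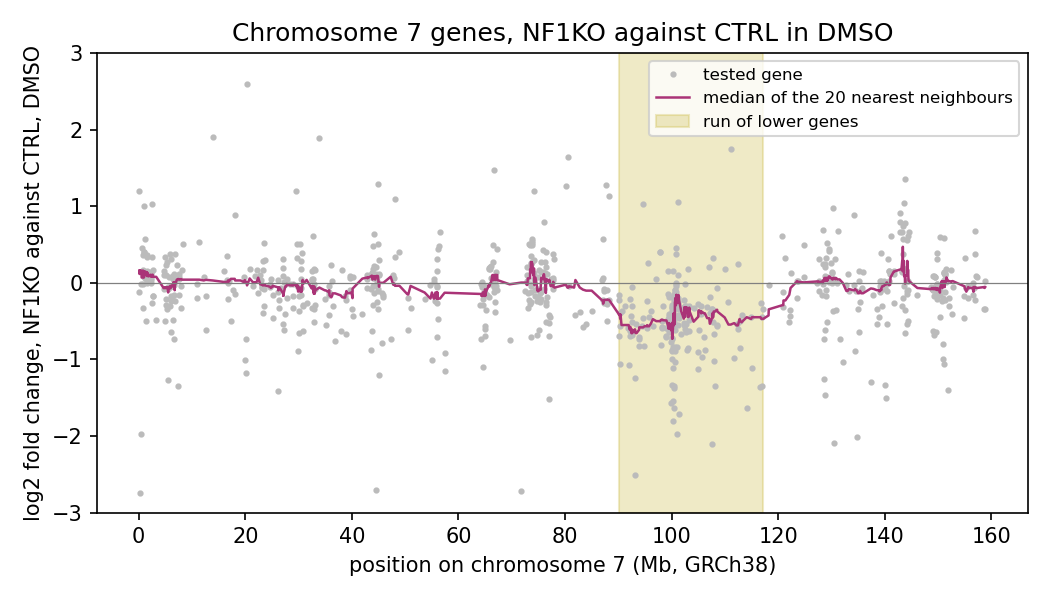
Log2 fold change between NF1KO and CTRL in DMSO (grey points) of 796 tested genes along chromosome 7 (position in Mb), with the median of the 20 nearest tested neighbours (line) and the stretch of lower genes (shaded). The 191 genes of the shaded stretch have a median of -0.48, and 9 genes lie outside the plotted range of -3 to 3.

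The comparison of BYL719 with DMSO in CTRL asks what PI3K alpha inhibition does to the control line. Each measured gene of the S phase and G2/M lists fell. CDC20 (Entrez 991, chromosome 1, 43358981 to 43363203), an activator of the anaphase-promoting complex, fell from 200 ± 9.76 CPM (SD, n = 3) to 55.3 ± 3.60 CPM (SD, n = 3), a log2 change of -1.85 ± 0.08 (adjusted p = 2.15e-08). KRT4 (Entrez 3851, chromosome 12, 52806549 to 52814116), a keratin, rose from 1.41 ± 0.239 CPM (SD, n = 3) to 23.4 ± 4.0 CPM (SD, n = 3), a log2 change of 4.05 ± 0.18 (adjusted p = 2.29e-08). TIMP3 (Entrez 7078, chromosome 22, 32801705 to 32863041), an inhibitor of matrix proteases, rose by 3.51 ± 0.10 (adjusted p = 1.52e-09).

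TGFB2 (3.26 ± 0.09), the scavenger receptor OLR1 (2.94 ± 0.11), RANBP3L (2.89 ± 0.22), PIP (2.82 ± 0.19), the carboxypeptidase CPA4 (2.80 ± 0.10), SYBU (2.56 ± 0.18) and HSD17B1 (2.49 ± 0.10), which forms estradiol, were among the other large rises. The other large falls were of the peroxisomal oxidase ACOX2 (-2.3 ± 0.10), the ganglioside-forming B4GALNT1 (-1.94 ± 0.15), the RNA-binding protein LIN28A (-1.90 ± 0.16), the cystine transporter SLC7A11 (-1.89 ± 0.30), the mitotic kinase PBK (-1.84 ± 0.08), SHCBP1 (-1.84 ± 0.11), PIR (-1.83 ± 0.09), CDKN3 (-1.81 ± 0.09) and the securin PTTG1 (-1.79 ± 0.09). Adjusted p values of these 16 genes lay between 1.35e-09 and 0.000297. In all, 3628 genes were higher and 3504 lower in BYL719, of which 826 and 650 by more than 2-fold. With a filter of at least 1 CPM in at least 3 libraries, 493 rather than 826 genes were more than 2-fold higher. The positions of TGFB2, HSD17B1, PBK and PIR overlap another gene with 20.3%, 114%, 39.4% and 65.6% of their counts.

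Each of the 27 measured G2/M and mitosis genes and each of the 27 S phase and DNA replication genes fell, also when adjusted over the list alone. The list tests gave an adjusted p of 1.34e-61 and 6.82e-41, and with an estimated correlation an adjusted p = 0.0126 and an adjusted p = 0.0364. The mitotic kinase PLK1 changed by -1.76 ± 0.06 and cyclin A2 (CCNA2), which overlaps a gene with 24.9% of its counts, by -1.68 ± 0.07, and the replication helicase subunit MCM2 by -1.12 ± 0.06, the ribonucleotide reductase subunit RRM1 by -1.13 ± 0.06 and the thymidine kinase TK1 by -1.55 ± 0.08. The list medians were -1.60 for G2/M and -1.19 for S phase.

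FOXO targets and PI3K feedback genes rose, with 15 of 20 higher and 0 lower, also when adjusted over the list alone (adjusted p = 5.04e-11 for the list, adjusted p = 0.0997 with an estimated correlation). The transcriptional co-regulator CITED2 rose by 1.96 ± 0.10, the ubiquitin ligase FBXO32 by 1.96 ± 0.11, CCNG2 by 1.38 ± 0.11 and the insulin receptor substrate IRS1 by 1.26 ± 0.07. ERBB2 rose by 1.23 ± 0.09 (adjusted p = 5.07e-07) within a receptor tyrosine kinase list of 4 rises and 5 falls in 16 (adjusted p = 0.580).

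Metabolic lists fell in CTRL, each of them without a call when the correlation was estimated. Glycolysis genes fell in 13 of 22 and rose in 2 (14 and 2 when adjusted over the list alone, adjusted p = 0.000570, adjusted p = 0.512 with an estimated correlation). GPI changed by -0.81 ± 0.06 and LDHA by -0.82 ± 0.07. Fatty acid synthesis genes fell in 10 of 15 with 0 rises, also when adjusted over the list alone (adjusted p = 0.000734, adjusted p = 0.0997 with an estimated correlation). The desaturase SCD changed by -0.95 ± 0.09 and ELOVL6 by -0.79 ± 0.06. Cholesterol synthesis and uptake genes fell in 12 of 23 and rose in 3 (13 and 3 when adjusted over the list alone, adjusted p = 0.0121, adjusted p = 0.600 with an estimated correlation). EBP changed by -1.03 ± 0.08. Oxidative phosphorylation subunits fell in 26 of 50 with 0 rises (27 and 0 when adjusted over the list alone, adjusted p = 0.000734, adjusted p = 0.845 with an estimated correlation). UQCRFS1 changed by -0.66 ± 0.07.

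Pentose phosphate pathway genes fell in 6 of 9 with 0 rises (7 and 1 when adjusted over the list alone, adjusted p = 0.0260, adjusted p = 0.512 with an estimated correlation). The transketolase TKT changed by -0.63 ± 0.06. The call of the list was lost without CTRL DMSO replicate 2 (adjusted p = 0.0552) or CTRL BYL719 replicate 1 (0.0648). NRF2 targets and glutathione synthesis genes fell in 13 of 19 and rose in 4, also when adjusted over the list alone (adjusted p = 0.0184, adjusted p = 0.388 with an estimated correlation). The quinone reductase NQO1 changed by -0.84 ± 0.09, while the thioredoxin reductase TXNRD1 rose by 0.69 ± 0.08. The call of the NRF2 list was lost without CTRL BYL719 replicate 1 (adjusted p = 0.0602) and without both CTRL number-1 libraries (0.0674). Integrated stress response and amino acid supply genes fell in 12 of 23 and rose in 3 (13 and 3 when adjusted over the list alone, adjusted p = 0.0108, adjusted p = 0.512 with an estimated correlation). The serine synthesis enzyme PHGDH changed by -0.97 ± 0.07 and the transcription factor ATF3 by 0.90 ± 0.07.

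The comparison of BYL719 with DMSO in NF1KO asks how the knockout line responded. Several of the largest rises were of genes that also rose in CTRL. KRT4 rose from 0.283 ± 0.035 CPM (SD, n = 2) to 2.35 ± 0.465 CPM (SD, n = 3), a log2 change of 3.04 ± 0.28 (adjusted p = 7.67e-05). TGFB2 (2.83 ± 0.17), TIMP3 (2.46 ± 0.11), the protease KLK10 (2.35 ± 0.31), PIP (2.29 ± 0.22), KRT23 (2.17 ± 0.11), SEMA6C (2.08 ± 0.23), NPNT (1.87 ± 0.12) and the iron reductase CYBRD1 (1.71 ± 0.18) rose as well. The falls were smaller, apart from SLC7A11 (Entrez 23657, chromosome 4, 138164097 to 138242349), which imports cystine for glutathione synthesis and fell from 45.9 ± 0.449 CPM (SD, n = 2) to 10.9 ± 2.93 CPM (SD, n = 3), a log2 change of -2.08 ± 0.31 (adjusted p = 0.00104).

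PLA2G4F (-1.21 ± 0.07), the nuclear receptor PPARG (-1.19 ± 0.14), IFRD1 (-1.18 ± 0.15), PIR (-1.16 ± 0.10), KREMEN2 (-1.11 ± 0.20), LRP8 (-1.05 ± 0.21), JPH2 (-1.05 ± 0.17), GRAMD1B (-1.04 ± 0.15) and the ceramidase ACER1 (-1.03 ± 0.16) made up the other largest falls. Adjusted p values of these 9 genes lay between 2.26e-06 and 0.00588, and without NF1KO DMSO replicate 3 the calls of KREMEN2 (adjusted p = 0.0572) and LRP8 (0.0583) were lost. IFRD1 lies in the chromosome 7 stretch described above, and TGFB2 and PIR overlap another gene with 20.3% and 65.6% of their counts. In all, 1652 genes were higher and 1362 lower, of which 340 and 73 by more than 2-fold. The count depended on the small groups: it was 615 higher and 433 lower without NF1KO DMSO replicate 2, 459 and 329 without replicate 3, and 1022 and 772 without NF1KO BYL719 replicate 2. With the filter of at least 1 CPM in at least 3 libraries, 214 and 38 genes were more than 2-fold higher and lower. These numbered 204 and 47 without NF1KO DMSO replicate 2 and 164 and 39 without replicate 3. It was 2764 and 2548 without both CTRL number-1 libraries, whose spread enters the shared estimate, and 3340 and 3456 with the block within each genotype, both added after the data were seen.

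FOXO targets and PI3K feedback genes rose in NF1KO in 14 of 20 with 0 falls (16 and 0 when adjusted over the list alone, adjusted p = 1.99e-19, adjusted p = 0.0323 with an estimated correlation). CITED2 rose by 1.64 ± 0.12, FBXO32 by 1.69 ± 0.13, IRS2 by 1.25 ± 0.12 and IRS1 by 0.73 ± 0.08. Integrated stress response and amino acid supply genes fell in 16 of 23 with 0 rises (19 and 1 when adjusted over the list alone, adjusted p = 3.06e-17, adjusted p = 0.0323 with an estimated correlation). CHAC1 changed by -2.00 ± 0.20, SLC7A5 by -0.93 ± 0.07, PHGDH by -0.68 ± 0.08 and SHMT2 by -0.57 ± 0.06. NRF2 targets and glutathione synthesis genes fell in 11 of 19 and rose in 2 (13 and 2 when adjusted over the list alone, adjusted p = 2.62e-07, adjusted p = 0.0323 with an estimated correlation). The heme oxygenase HMOX1 changed by -0.93 ± 0.09, NQO1 by -0.83 ± 0.10 and OSGIN1 by -0.95 ± 0.13.

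Estrogen receptor targets rose in 10 of 22 with 0 falls (11 and 0 when adjusted over the list alone, adjusted p = 1.18e-06, adjusted p = 0.0964 with an estimated correlation), among them the progesterone receptor PGR (0.99 ± 0.13), MYB (0.96 ± 0.09) and the kinase SGK3 (0.65 ± 0.07), which overlaps a gene with 101% of its counts. G2/M genes fell in 14 of 27 (18 when adjusted over the list alone, adjusted p = 2.60e-08, adjusted p = 0.283 with an estimated correlation). CDC20 changed by -0.69 ± 0.08 and PLK1 by -0.56 ± 0.07. S phase genes fell in 2 of 27 (0 when adjusted over the list alone, adjusted p = 0.000714, adjusted p = 0.667 with an estimated correlation and 0.0785 with fry). TK1 changed by -0.32 ± 0.09 and MCM5 by -0.21 ± 0.07.

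Among metabolic lists, cholesterol synthesis and uptake genes fell in 10 of 23 with 0 rises (16 and 0 when adjusted over the list alone, adjusted p = 5.67e-08, adjusted p = 0.142 with an estimated correlation). STARD4, a sterol carrier, changed by -0.70 ± 0.10. Glycolysis genes fell in 8 of 22 with 0 rises (12 and 0 when adjusted over the list alone, adjusted p = 2.34e-05, adjusted p = 0.328 with an estimated correlation), and pentose phosphate pathway genes in 5 of 9 with 0 rises (5 and 1 when adjusted over the list alone, adjusted p = 0.000174, adjusted p = 0.129 with an estimated correlation). TKT changed by -0.75 ± 0.06. Oxidative phosphorylation subunits fell in 11 of 50 with 0 rises (14 and 0 when adjusted over the list alone, adjusted p = 6.28e-06, adjusted p = 0.776 with an estimated correlation and 0.20 with fry). Fatty acid synthesis genes fell in 7 of 15, and FADS1, which overlaps FADS2 with 377% of its counts, rose by 0.43 ± 0.07 (the same counts when adjusted over the list alone, adjusted p = 0.000746, adjusted p = 0.0964 with an estimated correlation). Peroxide and superoxide detoxification genes fell in 5 of 19 with 0 rises (6 and 2 when adjusted over the list alone, adjusted p = 0.0219, adjusted p = 0.776 with an estimated correlation). The peroxidase GPX3 changed by -0.68 ± 0.10, and the call of the list was lost without NF1KO BYL719 replicate 2 (adjusted p = 0.0636), with the replicate block (0.141) and with fry (0.20). Hypoxia response genes rose in 5 of 18 and fell in 1 (6 and 1 when adjusted over the list alone, adjusted p = 0.0431, adjusted p = 0.339 with an estimated correlation). NDRG1 changed by 1.53 ± 0.19. The hypoxia call was lost without NF1KO DMSO replicate 3 (adjusted p = 0.108) or NF1KO BYL719 replicate 1 (0.0522).

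Most genes called with BYL719 in NF1KO were also called in CTRL. Of 1652 genes raised in NF1KO and 3628 in CTRL, 1341 were shared (81.2% of the former), where 373 would be if the calls were independent. Of 1362 lowered in NF1KO and 3504 in CTRL, 1054 were shared (77.4% of the former), against 297. Only 47 genes were called in opposite directions, and the fold changes correlated across genes with a Pearson r of 0.61, genes not being independent replicates. KRT4, TGFB2, TIMP3 and PIP were among the largest rises, and SLC7A11 and PIR among the largest falls, in both.

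The comparison of NF1KO with CTRL in BYL719 asks what set the lines apart under drug. Most ERK output genes stayed higher in NF1KO, with a list median of 0.98, and most measured cell-cycle genes were higher as well. The S phase and G2/M lists were not called with an estimated correlation (adjusted p = 0.0876 and 0.0668). TRIM55 (Entrez 84675, chromosome 8, 66113351 to 66175485) rose by 6.90 ± 0.22 (adjusted p = 3.93e-10), SPRY4 by 6.36 ± 0.24 (adjusted p = 2.11e-09) and ETV5 by 6.28 ± 0.21 (adjusted p = 7.27e-10). CALCR fell by 5.78 ± 0.12 on the log2 scale (adjusted p = 2.50e-11), and TGFB2 stood at 72.2 ± 5.47 CPM (SD, n = 3) in CTRL and 1.96 ± 0.169 CPM (SD, n = 3) in NF1KO, a log2 change of -5.20 ± 0.10 (adjusted p = 1.31e-11).

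The other large rises were of AOC1 (6.27 ± 0.19), DOK7 (6.12 ± 0.24), CLSTN2 (5.87 ± 0.16), the neuroendocrine transcription factor INSM1 (5.56 ± 0.23), the immediate early factor EGR3 (5.03 ± 0.28), the potassium channel subunit KCNE4 (5.0 ± 0.15) and FGD5 (4.93 ± 0.24). Other large falls included those of ARMCX1 (-5.45 ± 0.16), VCAN (-4.94 ± 0.17), PHACTR1 (-4.12 ± 0.10), OLR1 (-4.07 ± 0.12), GNG11 (-3.88 ± 0.11) and the tight junction protein CLDN1 (-3.82 ± 0.10). Adjusted p values of these 13 genes lay between 6.52e-11 and 5.45e-08. In all, 3343 genes were higher and 3061 lower, of which 795 and 779 by more than 2-fold. With a filter of at least 1 CPM in at least 3 libraries, 502 rather than 779 genes were more than 2-fold lower. CALCR and GNG11 lie in the chromosome 7 stretch described above, and TGFB2 and PHACTR1 overlap another gene with 20.3% and 241% of their counts.

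Of the 27 S phase genes 26 were higher and 0 lower (27 and 0 when adjusted over the list alone, adjusted p = 1.26e-25, adjusted p = 0.0876 with an estimated correlation), and of the 27 G2/M genes 24 and 0, also when adjusted over the list alone (adjusted p = 7.25e-29, adjusted p = 0.0668 with an estimated correlation). PLK1 was higher by 1.47 ± 0.06, CCNA2 by 1.42 ± 0.07, TK1 by 1.40 ± 0.08 and MCM2 by 1.10 ± 0.06. ERK output genes were higher in 15 of 20 and lower in 3 (16 and 3 when adjusted over the list alone, adjusted p = 1.12e-18, adjusted p = 0.00998 with an estimated correlation). DUSP4 changed by 3.78 ± 0.08 and DUSP6 by 4.66 ± 0.19.

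Hypoxia response genes were lower in 9 of 18 and higher in 1, also when adjusted over the list alone (adjusted p = 0.00280, adjusted p = 0.198 with an estimated correlation). ADM changed by -3.11 ± 0.16 and NDRG1 by -2.53 ± 0.16. Receptor tyrosine kinases were lower in 9 of 16 and higher in 4, also when adjusted over the list alone (adjusted p = 0.0110, adjusted p = 0.138 with an estimated correlation). ERBB2 changed by -1.67 ± 0.09 and FGFR2 by -1.48 ± 0.08, and RET rose by 1.07 ± 0.08. The list of RAS GTPase-activating proteins, NF1 included, was lower in 4 of 11 and higher in 1, also when adjusted over the list alone (adjusted p = 0.0271, adjusted p = 0.737 with an estimated correlation). Its call was lost when NF1 was left out of it (adjusted p = 0.646). RASA3 changed by -0.91 ± 0.10. Luminal identity genes were lower in 8 of 15 and higher in 1 (10 and 1 when adjusted over the list alone). ELF3 changed by -0.87 ± 0.11, and the list was not called (adjusted p = 0.118). It was called with the replicate block (adjusted p = 0.0390), without both CTRL number-1 libraries (0.0277) and without CTRL BYL719 replicate 1 (0.0460).

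Most genes that differed between the lines in DMSO also differed in BYL719, and most that differed in BYL719 were not called in DMSO. The NF1KO group held 2 libraries in DMSO and 3 in BYL719, so a gene not called in DMSO may still differ there. Of 1607 genes higher in DMSO and 3343 in BYL719, 1155 were shared (34.5% of the latter), where 334 would be if the calls were independent. Of 1662 genes lower in DMSO and 3061 in BYL719, 1277 were shared (41.7% of the latter), against 316. Opposite directions were called for 69 genes. Fold changes correlated across genes with a Pearson r of 0.77. SPRY4, ETV5, TRIM55, AOC1, DOK7 and CLSTN2 were among the largest rises in both.

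The difference of the BYL719 effect between NF1KO and CTRL asks for which genes the drug acted differently in the knockout and control lines. Genes of DNA replication and mitosis were lowered by BYL719 in CTRL, and by less in NF1KO. MCM2 (Entrez 4171) fell from 188 ± 5.48 to 87.0 ± 3.05 CPM (SD, n = 3 each) in CTRL and stood at 204 ± 4.93 CPM (SD, n = 2) and 186 ± 4.55 CPM (SD, n = 3) in NF1KO, a log2 difference of the effects of 0.99 ± 0.08 (adjusted p = 3.48e-05). For PLK1 (Entrez 5347) the difference of the effects was 1.2 ± 0.09 (adjusted p = 2.62e-05). Of the 27 G2/M genes 24 had a higher and 0 a lower effect in NF1KO, also when adjusted over the list alone (median 1.25, adjusted p = 4.35e-75, adjusted p = 0.00945 with an estimated correlation). Of the 27 S phase genes these were 25 and 0 (26 and 0 when adjusted over the list alone; median 1.07, adjusted p = 7.96e-55, adjusted p = 0.0186 with an estimated correlation). TYMS changed by 1.21 ± 0.12 and CDC45 by 1.24 ± 0.12.

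**Figure D4:**
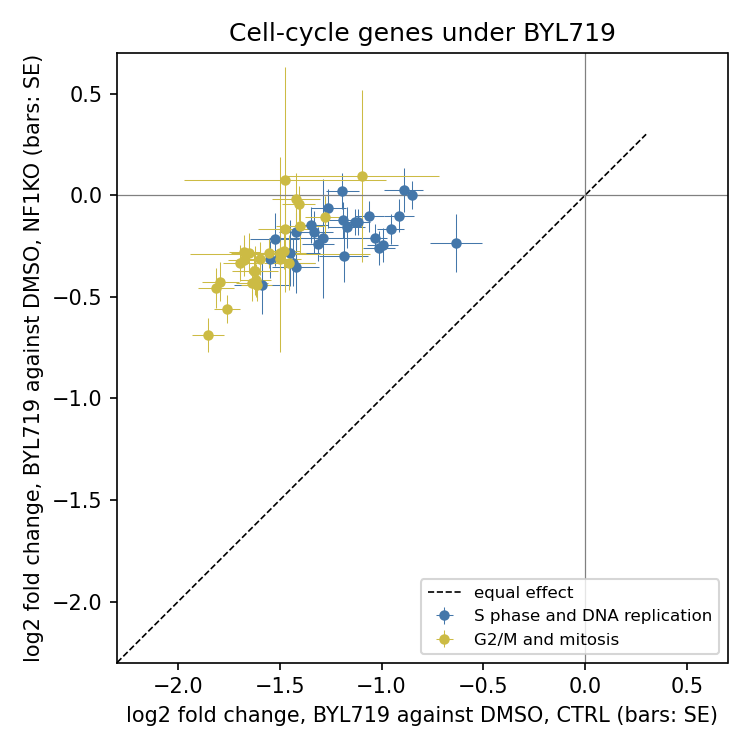
Log2 fold change of BYL719 against DMSO in CTRL (horizontal axis) and in NF1KO (vertical axis) for 27 S phase and 27 G2/M genes (points, with SE bars), with a dashed line of equal effect. Each gene fell in CTRL, with list medians of -1.19 and -1.60, and the points lie above the dashed line, with list medians of -0.18 and -0.31 in NF1KO.

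Single genes whose effect was higher in NF1KO were led by the transcription factor GATA4 (1.95 ± 0.17), which fell in CTRL from 9.03 ± 0.273 to 2.77 ± 0.275 CPM (SD, n = 3 each) and stood at 12.1 ± 0.355 CPM (SD, n = 2) and 14.3 ± 2.07 CPM (SD, n = 3) in NF1KO. EGR3 (1.86 ± 0.39), the spindle protein HAUS1 (1.81 ± 0.11), ACOX2 (1.68 ± 0.14), the PCNA-binding PCLAF (1.58 ± 0.12), the mitotic kinesin KIF15 (1.58 ± 0.41), the proteoglycan GPC3 (1.54 ± 0.21), the mitotic phosphatase CDC25C (1.52 ± 0.12), NEURL1B (1.49 ± 0.13) and the kinesin KIF18A (1.46 ± 0.20) followed. The effect was lower in NF1KO for CPA4 (-2.46 ± 0.14), which rose in CTRL from 6.03 ± 0.880 to 41.9 ± 0.739 CPM (SD, n = 3 each) and stood at 11.9 ± 0.624 CPM (SD, n = 2) and 15 ± 0.383 CPM (SD, n = 3) in NF1KO. HSD17B1 (-2.23 ± 0.14), the sphingolipid transporter SPNS2 (-2.08 ± 0.16), the adhesion molecule L1CAM (-2.05 ± 0.15), TRIM29 (-1.96 ± 0.17), TM4SF1 (-1.85 ± 0.18), HS3ST3B1 (-1.84 ± 0.22), the netrin NTN4 (-1.67 ± 0.25), ID3 (-1.64 ± 0.20) and the keratin KRT80 (-1.64 ± 0.12) followed. Adjusted p values of these 20 genes lay between 9.00e-06 and 0.0303. The call of EGR3 was lost without NF1KO DMSO replicate 2 (adjusted p = 0.0503). That of KIF15 was lost without CTRL BYL719 replicate 2 (0.0679) or 3 (0.0601), NF1KO DMSO replicate 2 (0.145) or 3 (0.0994), and NF1KO BYL719 replicate 1 (0.0638), 2 (0.0682) or 3 (0.0543). The positions of HSD17B1, SPNS2 and CDC25C overlap another gene with 114%, 406% and 464% of their counts.

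In all, 914 genes had a higher and 596 a lower effect in NF1KO. Of these 1510 genes, 854 had been lowered by BYL719 in CTRL, 847 of them with the higher effect in NF1KO, and 657 of the 854 were not called in NF1KO. Another 527 had been raised in CTRL, 520 of them with the lower effect in NF1KO. Opposite directions in the lines were called for 47, and 113 were called in NF1KO alone. The CTRL effect is itself subtracted in the difference, so genes chosen by both calls tend to these directions in any case. Those directions are therefore no separate evidence of a weaker response. A gene not called in NF1KO, whose DMSO group held 2 libraries, may still have responded. Without NF1KO DMSO replicate 2 the counts were 523 higher and 243 lower, without replicate 3 they were 495 and 245, and the lower effects numbered 377 without CTRL DMSO replicate 2 and 922 without CTRL BYL719 replicate 1. Added after the data were seen, leaving out both CTRL number-1 libraries gave 1393 and 1018, and the block within each genotype 2225 and 2203.

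Estrogen receptor targets had a higher effect of BYL719 in NF1KO in 8 of 22 and a lower in 1 (10 and 2 when adjusted over the list alone; median 0.28, adjusted p = 0.00534, adjusted p = 0.498 with an estimated correlation). The effect on SGK3, whose position overlaps another gene with 101% of its counts, differed by 0.70 ± 0.10 and that on RERG by 0.77 ± 0.12, while KRT13 had a difference of -1.85 ± 0.29. Integrated stress response genes had a lower effect in 5 of 23 (7, and 1 higher, when adjusted over the list alone; median -0.13, adjusted p = 0.00437, adjusted p = 0.498 with an estimated correlation). The effect on CHAC1 differed by -2.32 ± 0.28 and that on ATF3 by -0.68 ± 0.11. That on DDIT3, which overlaps a gene with 1867% of its counts, differed by -0.75 ± 0.16. Between the lines the median of the integrated stress response list was 0.31 in DMSO. In BYL719 it was 0.11, and the list was not called there by camera (adjusted p = 0.963). A higher starting level in NF1KO was therefore not told apart from a stronger drug effect. Luminal identity genes had a lower effect in 3 of 15 and a higher in 1 (5 and 1 when adjusted over the list alone; median -0.15, adjusted p = 0.0243, adjusted p = 0.498 with an estimated correlation). The effect on ELF3 differed by -0.72 ± 0.16 and that on ESR1 by 0.44 ± 0.12. FOXO targets were not called as a list (adjusted p = 0.413). IRS1 changed by -0.52 ± 0.10, BCL6 by -0.58 ± 0.15 and the kinase PDK4, which lies in the chromosome 7 stretch, by 1.38 ± 0.29.

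The BYL719 response score condensed the drug effect to a single value per library, the mean log2 CPM of 1372 genes raised by BYL719 over both lines less that of 856 genes lowered. The score rose from -2.25 ± 0.0607 to 0.109 ± 0.116 (SD, n = 3 each) in CTRL, and from -2.61 ± 0.0401 (SD, n = 2) to -1.26 ± 0.0261 (SD, n = 3) in NF1KO. The effect was 2.36 in CTRL and 1.35 in NF1KO, a difference of -1.01 (2-sided permutation p = 0.005, the smallest that 200 arrangements of the residuals can give). Those arrangements ignore any pairing of libraries by replicate number. With pairs kept together the difference was -1.01 and no longer called (permutation p = 0.1, the smallest that 10 arrangements can give). Raised genes rose in NF1KO by 69.6% of their rise in CTRL, and lowered genes fell by 44.8% of their fall.

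**Figure D5:**
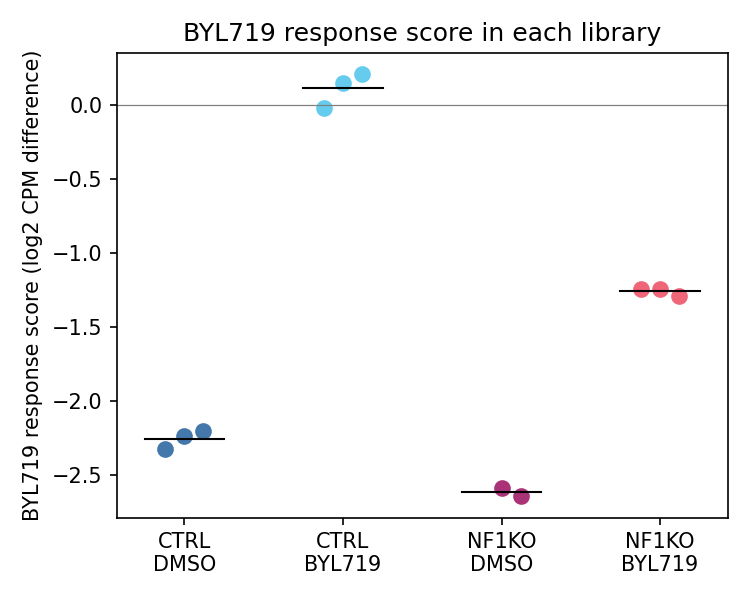
BYL719 response score of each library (points, log2 CPM difference) with the mean of each group (lines). The 3 CTRL BYL719 libraries lie between -0.02 and 0.21 and the 3 NF1KO BYL719 libraries between -1.29 and -1.24, and the DMSO libraries of both lines lie below -2.20.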

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

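The tests of a shared day, of a lower starting level and of copy number on chromosome 7 were chosen after the results were seen, as were the settings without both CTRL number-1 libraries, with the block within each genotype and with NF1 left out of its list.

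A test of the difference itself gave 914 genes with a higher and 596 with a lower effect of BYL719 in NF1KO. The response score differed by -1.01. With pairs kept together it was not called (permutation p = 0.1, the smallest that 10 arrangements can give), in a test that could not reach 0.05. By camera on the difference of effects 5 lists differed. Their medians were 1.07 for S phase, 1.25 for G2/M, 0.28 for estrogen receptor targets, -0.13 for integrated stress response and -0.15 for luminal identity. The last 3 of these calls were lost with an estimated correlation (adjusted p = 0.498 each). The named genes with a higher effect in NF1KO were GATA4 (1.95), EGR3 (1.86), HAUS1 (1.81), ACOX2 (1.68), PCLAF (1.58), KIF15 (1.58), GPC3 (1.54), CDC25C (1.52), NEURL1B (1.49) and KIF18A (1.46). Those with a lower effect were CPA4 (-2.46), HSD17B1 (-2.23), SPNS2 (-2.08), L1CAM (-2.05), TRIM29 (-1.96), TM4SF1 (-1.85), HS3ST3B1 (-1.84), NTN4 (-1.67), ID3 (-1.64) and KRT80 (-1.64). The calls of EGR3 (adjusted p = 0.0503) and KIF15 (0.145) were lost without NF1KO DMSO replicate 2, and that of KIF15 also without NF1KO DMSO replicate 3 (0.0994), CTRL BYL719 replicate 2 (0.0679) or 3 (0.0601), or NF1KO BYL719 replicate 1 (0.0638), 2 (0.0682) or 3 (0.0543).

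The smaller fall of cell-cycle mRNAs under BYL719 in NF1KO had a median difference of 1.19 over 54 list members (quartiles 1.07 and 1.25). It did not come from the CTRL number-1 libraries alone, since the median was 1.26 without both, nor from a single NF1KO DMSO library, since it was 1.18 and 1.2 with either left out. A lower starting level in NF1KO is argued against by a median difference of -0.047 in DMSO (quartiles -0.16 and 0.08). Continued cycling of NF1KO cells under BYL719 is a hypothesis left untested, since neither cell numbers nor DNA content was analysed here, as is any difference between the lines other than NF1, since how the lines were made was not stated.

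The knockout and control lines differed in many mRNAs in DMSO. Copy-number differences as the cause of the whole pattern are argued against by the small share of called genes that moved with their neighbours. This share was 5.95% of the 3261 called genes with a position (95% exact interval 5.16% to 6.82%). For these genes the 20 nearest tested neighbours had a median change of the same sign and at least 50% of the size of their own. The interval treats genes as independent, although nearby genes share neighbours, so it is likely too narrow. The share was 8.00% for the lines in BYL719, 5.48% and 3.03% for BYL719 in CTRL and NF1KO, and 1.13% for the difference of effects. Correlations with the median of neighbours across genes were 0.18 and 0.16 for the lines and 0.094 and 0.096 for BYL719. For the difference of effects, in which a fixed copy-number difference would cancel, the correlation was 0.16. A correlation of this size is therefore no sign of copy number by itself, and copy number as the cause of a small part stays open. For the chromosome 7 stretch (90119400 to 117230176) a lower copy number in NF1KO may be the cause. Its more highly expressed genes had a median of -0.43 (quartiles -0.61 and -0.28), the 5 NF1KO libraries lay between -0.55 and -0.46, and BYL719 moved it by 0.04 in CTRL and 0.03 in NF1KO. The 11449 windows of 191 genes elsewhere had medians from -0.13 to 0.12, but windows of that size can hide shorter runs. The stretch was the longest of 9 runs of genes moving together, higher or lower. Another of them, with 23 tested genes on chromosome 14, had medians of -0.49 in DMSO and -0.51 in BYL719. DNA was not analysed here.

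The CTRL number-1 libraries stood apart from the other CTRL libraries in both treatments, with deviations correlated at 0.59 across genes. GC content and transcript length as the whole cause are argued against, since the correlation was 0.54 after their trend was taken out. A day shared by all number-1 libraries could not be decided from the single such NF1KO library, whose deviations correlated with theirs at 0.0834 and 0.0609. No biological explanation was tested.

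For BYL719 against DMSO in CTRL, 1 of the 10 splits of the 6 libraries gave as many called genes, the real split with 7132, and the highest of the others was 0 with edgeR, with up to 2301 genes at an unadjusted p under 0.05 against 8246. For NF1KO against CTRL in BYL719 this was also 1 of 10, with 6404 and 0, and up to 2051 against 7735 at an unadjusted p under 0.05. Splits of 3 against 3 are too few for a share under 0.05. A split that mixes the groups also turns the real difference into spread within its groups. Few calls then follow in any case, so the contrast with the real split is no measure of chance. In CTRL, the 3 other splits that part all 3 same-number pairs gave 84, 83 and 100 genes at an unadjusted p under 0.05.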

How the results depend on the processing

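The block within each genotype and the settings without both CTRL number-1 libraries and with NF1 left out of its list were chosen after the data were seen. Where a call or direction changed the cause was not tested, except that the stricter filter tests fewer genes and leaving out a library leaves fewer samples.

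No gene called in a comparison was called in the opposite direction under an alternative. Over lists, comparisons and alternatives, 1297 results kept their direction and side of the threshold, 48 lost a call, 30 gained one and 80 reversed, and for named genes these were 9139, 402, 148 and 6. Counts of called genes stayed within 1.5 times in 291 cases and moved further in 37.

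With the replicate number as a block, which allows for pairing, genes higher and lower with BYL719 in NF1KO numbered 2503 and 2161. The block reversed basal (adjusted p = 0.964) and lysosome genes (0.982) in NF1KO against CTRL in BYL719. In the difference of effects it reversed RAS GTPase-activating proteins (0.925), hypoxia response (0.994), peroxide detoxification, apoptosis regulators and other-cell-type markers (0.893 each). It ended the calls of apoptosis regulators in DMSO (0.0522) and peroxide detoxification with BYL719 in NF1KO (0.141), and gave calls of ribosome biogenesis in DMSO (0.0351) and with BYL719 in NF1KO (0.00539) and of luminal identity in BYL719 (0.0390). The block changed no other list call. The score difference was -1.01 with 3 CTRL and 2 NF1KO pairs kept together, with a permutation p of 0.1, the smallest that 10 arrangements can give.

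With the block within each genotype, genes higher and lower numbered 3340 and 3456 for BYL719 in NF1KO and 2225 and 2203 for the difference of effects. NF1 with BYL719 in NF1KO changed to -0.021. For NF1KO against CTRL in DMSO the counts were 2753 and 2774. That fit compares the lines at replicate 3 alone, so these are not an alternative count of the line difference.

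Without both CTRL number-1 libraries, genes higher and lower numbered 2764 and 2548 for BYL719 in NF1KO and 1393 and 1018 for the difference of effects. Reversed lists were oxidative phosphorylation (0.965) and cholesterol synthesis (0.822) in DMSO, immediate early genes with BYL719 in NF1KO (0.898), and peroxide detoxification (0.913) and lysosome genes (0.832) in BYL719. In the difference of effects these were the pentose phosphate pathway, basal markers and apoptosis regulators (0.953 each) and other-cell-type markers (0.991), and CD14 reversed to 0.21. Ribosome biogenesis was called in DMSO (0.00447) and with BYL719 in NF1KO (0.0330).

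With the stricter filter, genes more than 2-fold higher numbered 300 for NF1KO against CTRL in DMSO, 493 for BYL719 in CTRL and 214 for BYL719 in NF1KO, and genes more than 2-fold lower 38 for BYL719 in NF1KO and 502 for NF1KO against CTRL in BYL719. RLE scaling reversed the pentose phosphate pathway and other-cell-type markers (0.976 each) in the difference of effects, and gave a call of ribosome biogenesis with BYL719 in NF1KO (0.0478). Fry reversed RAS GTPase-activating proteins with BYL719 in NF1KO (0.934), and in the difference of effects hypoxia response (0.994), apoptosis regulators and other-cell-type markers (0.909 each). With BYL719 in NF1KO fry ended the calls of oxidative phosphorylation and peroxide detoxification (0.20 each) and S phase (0.0785). Fry, which does not compare a list with other genes, gave calls that camera did not. In DMSO these were the pentose phosphate pathway (0.0289) and immediate early genes (0.000129). With BYL719 in CTRL they were receptor tyrosine kinases (0.0183), hypoxia response (0.00126), luminal identity (0.00247), basal markers (0.0394), lysosome genes (0.0491) and immediate early genes (0.000492). In NF1KO against CTRL in BYL719 they were FOXO targets (0.0194), the pentose phosphate pathway (0.00733), fatty acid synthesis (0.00850), estrogen receptor targets (0.0447), apoptosis regulators (0.00176), luminal identity and immediate early genes (0.00151 each). In the difference of effects they were fatty acid synthesis (0.0226) and immediate early genes (0.0324).

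Leaving NF1 out of the RAS GTPase-activating proteins ended the calls of that list in DMSO (adjusted p = 0.567) and in BYL719 (0.646), which the level of NF1 itself had carried. It reversed the list, uncalled, with BYL719 in CTRL (0.978) and in the difference of effects (0.927).

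Leaving out each library in turn, NF1KO against CTRL in DMSO had 744 to 1286 genes higher and 779 to 1408 lower. BYL719 in NF1KO had 459 to 1593 higher and 329 to 1301 lower, and more than 2-fold 164 to 310 higher and 39 to 72 lower. The difference of effects had 495 to 1233 higher and 243 to 922 lower. Lowest counts came without NF1KO DMSO replicate 3, except for the lower effects, without replicate 2.

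Lists that reversed when a library was left out had these lowest and highest adjusted p. In DMSO they were oxidative phosphorylation 0.245 to 0.915, cholesterol synthesis 0.446 to 0.915, S phase 0.608 to 0.944 and interferon response 0.524 to 0.996. With BYL719 in CTRL they were RAS GTPase-activating proteins 0.481 to 0.983, ribosome biogenesis 0.298 to 0.899, antigen presentation 0.479 to 0.979 and other-cell-type markers 0.713 to 0.988. With BYL719 in NF1KO they were RAS GTPase-activating proteins 0.726 to 0.961, basal markers 0.628 to 0.961, immediate early genes 0.726 to 0.998 and other-cell-type markers 0.551 to 0.955. NF1 there ranged from -0.0056 to 0.60 and VWF from -0.87 to 0.034.

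In NF1KO against CTRL in BYL719 they were NRF2 targets 0.844 to 0.998, peroxide detoxification 0.683 to 0.987, integrated stress response 0.750 to 0.998, basal markers 0.763 to 0.990, interferon response 0.607 to 0.918, antigen presentation 0.607 to 0.998 and lysosome genes 0.837 to 0.998. In the difference of effects they were RAS GTPase-activating proteins 0.632 to 0.987, hypoxia response 0.780 to 0.981, pentose phosphate pathway 0.780 to 0.987, peroxide detoxification 0.452 to 0.987, oxidative phosphorylation 0.0842 to 0.922, basal markers 0.623 to 0.985, interferon response 0.254 to 0.942, antigen presentation 0.546 to 0.987, apoptosis regulators 0.780 to 0.987 and other-cell-type markers 0.630 to 0.990. CD68 there ranged from -0.38 to 0.022 and CD14 from -0.78 to 0.19.

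With an estimated correlation, the calls that held were 1 of 6 in DMSO (ERK output), 2 of 10 with BYL719 in CTRL (S phase, G2/M), 3 of 13 with BYL719 in NF1KO (FOXO targets, NRF2 targets, integrated stress response), 1 of 6 in BYL719 (ERK output) and 2 of 5 in the difference of effects (S phase, G2/M). The score difference ranged from -1.14 to -0.91 with a library left out. Its size depended on how its genes were chosen. It was -0.485 with genes chosen by adjusted p alone and -1.18 with a fold above 2.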

Other observations

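Of the 25 measured lists, 7 were called by camera at the preset correlation in no comparison. Interferon response genes, with 17 measured, had adjusted p values between 0.255 and 0.824, antigen presentation genes (14) between 0.666 and 0.996, and basal and mesenchymal markers (12) between 0.666 and 0.973. Lysosome and autophagy genes (27) lay between 0.146 and 0.963, immediate early and heat shock genes (17) between 0.184 and 0.858, and markers of fibroblasts, endothelium and blood cells (9) between 0.393 and 0.996. Ribosome biogenesis genes (23), which serve cell growth, lay between 0.0516 and 0.646. Fry called immediate early genes in DMSO (adjusted p = 0.000129), with BYL719 in CTRL (0.000492), in BYL719 (0.00151) and in the difference of effects (0.0324), and basal markers (0.0394) and lysosome genes (0.0491) with BYL719 in CTRL. Camera called the ribosome biogenesis list in DMSO without CTRL DMSO replicate 1 (0.00586), without both CTRL number-1 libraries (0.00447) and with the replicate block (0.0351). With BYL719 in NF1KO it did so without NF1KO DMSO replicate 2 (0.0269) or NF1KO BYL719 replicate 1 (0.0455), without both CTRL number-1 libraries (0.0330), with the replicate block (0.00539) and with RLE scaling (0.0478). The interferon list was called with BYL719 in NF1KO without NF1KO DMSO replicate 2 (0.0406), and the lysosome list with BYL719 in CTRL without CTRL BYL719 replicate 1 (0.0400).

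The smaller response score in NF1KO was set against the hypothesis that the difference is limited to the cell-cycle list members. Genes raised by BYL719 rose in NF1KO by 69.6% of their rise in CTRL (68.4% to 70.7% with a library left out), which argues against it. They held 0 list members, and each of those fell in CTRL. Genes outside the lists may follow the cell cycle too, so a difference in cycling between the lines was not told apart from other causes. Lowered genes fell by 44.8% of their fall in CTRL, by 46.6% over the 810 outside the cell-cycle lists and by 18.7% over the 46 list members.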
